A study of Paracentrotus lividus with 54 samples.

How the data were processed

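The series holds 54 samples of Paracentrotus lividus: 22 RNA-seq, 28 ATAC-seq and 4 CUT&Tag. The deposited gene table holds whole-number read counts per gene model for the 22 RNA libraries. Per the labels' protocols, RNA was extracted with Trizol and strand-specific libraries were sequenced as paired 150-base reads. Per the submitters' processing notes, reads were aligned with STAR 2.5.2b and counted with featureCounts 1.6.1, and the file header gives strand option 1 and no option for counting pairs. Which strand the kit's reads follow is not given in the sources used here and was not tested, so counts may come from the strand opposite to the transcript. The genome build is not given in the sources used here, and coordinates are those of the deposited files, printed 1-based. In 21 of the 22 libraries every count was even, while in bodywall 52.4% of nonzero counts were odd, so printed count intervals used counts divided by 2 where all were even. A floor of 3 counts per library, after the same division, stands for a count of 0, and lower bounds of folds put it in each of the 4 libraries at 0; the division was chosen after seeing the data. This floor is between 0.165 and 0.381 CPM.

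The deposited ATAC lists give, per peak, an area score and a -log10 p-value made by the authors. Per the submitters' processing notes, Bowtie2 2.4.1 and Genrich were used. The score is the authors' own value and served only to rank or filter peaks. Lists are named for a stage and all its samples, so peaks were taken as called on pooled samples. Per the labels' protocols, different numbers of nuclei were tried per stage. CUT&Tag samples were not analysed here.

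Samples were grouped by stage or tissue from the labels. The trend was fitted in edgeR 4.0.16 (R 4.3.3) to the counts of 17 developmental libraries, with TMM scaling, filterByExpr and a natural spline with 4 degrees of freedom on stage order, leaving 12 residual degrees of freedom. Libraries of 1 stage each cannot separate culture from stage, so p-values measure scatter around the curve. All spline terms were tested for a trend, and the mean of the curve over the last 4 minus the first 4 stages for direction, with Benjamini-Hochberg adjustment at 0.05 and a log2 change of 1. Fitted changes of genes with 0 counts at one end are no bound, and lower bounds are given for those named.

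On simulated counts for 22940 genes the trend test called 75 of 100 genes changed 4-fold, 4 of 100 changed 2-fold and 0 of 22740 unchanged genes. The contrast called 78, 7 and 1. All of its calls on changed genes had the right sign, and the median estimate for 4-fold genes was 1.95 against a true log2 contrast of 1.93. A minimum of 80 calls among the 4-fold genes, set before the simulation was run, was not met. A lower minimum was set after this result and then withdrawn, and the conditions on sign and false calls that the simulation had to meet were also set after it. The fit was kept as designed, and the shortfall is a limit on its power. The changed genes were drawn from those with a mean above 100 counts and followed the same curve shape. Scatter was drawn independently for each library. Power for genes with fewer counts, and false calls under scatter shared between genes of a library, were therefore not measured.

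Medians of gene classes are TMM-scaled CPM, and levels of named genes are CPM of the library total. Step changes needed a ratio of 4 in TMM-scaled CPM, 5 CPM in the higher library and a prior of 0.5 CPM. Tissue-restricted genes needed 5 CPM and 8 times the next adult tissue. Peak lists were compared with bedtools 2.31.1, with an overlap of at least 50% of the shorter peak. Summits within 1 kb of an annotated gene start counted as near it, and gain or loss of a start peak means gain or loss of such a summit, whether or not the peaks of both lists overlap. Binomial intervals are Clopper-Pearson. Genes that gained or lost a start peak were set against 10000 random lists matched in 20 bins of mean log2 CPM. In simulations of this step on 22940 genes, 0 of 10 unchanged lists and 10 of 10 lists moved by 0.3 fell outside the central 95%. Changes there were drawn independently for each gene and without regard to its level, and the lists were random genes of a single size. The effect of matching, of changes shared between genes, and of smaller lists or shifts was therefore not measured.

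Tests, alternatives and the rule for named genes were set before the data were examined, apart from those said to be chosen later. The rule took, in the absence of gene names, the 2 rising and 2 falling identifiers with the largest fitted change, an adjusted p under 0.05, at least 20 CPM in 1 library and no overlap between the first and last 4 libraries. The 19 gene lists fixed beforehand were not used here, since they need names. For the similarity of egg and ovaries the filter had not been spelled out for 22 libraries: a filter over all 22 was used first, and the genes of the trend test were taken as the main set only after values under both that filter and another had been seen. The values of all 4 gene sets are given. Alternatives were RLE scaling, other filters, a 3-degree spline, log2 hours, DESeq2 1.42.0, limma-voom (limma 3.58.1), each library left out, other windows, overlaps and list lengths.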

Results

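The study followed the sea urchin Paracentrotus lividus from the egg to the pluteus larva, the feeding larva with arms, and added 5 adult tissues. RNA-seq covered 22 libraries, 1 per stage or tissue: 17 developmental libraries between 0 and 48 hours after fertilization, and adult ovaries, gut, bodywall, tubefeet and Aristotle's lantern, the chewing apparatus. Deposited library totals ran from 14657193 counts in bodywall to 36305776 in ovaries. Every count was even in the other 21 libraries but not in bodywall, so the bodywall total may be in another unit. The totals therefore do not rank bodywall by sequencing depth. Of the 33922 gene models 2836 had no count in any library. ATAC-seq, which marks open chromatin by transposase insertion, covered 28 samples at 6 stages and was read here as 1 peak list per stage. The 4 CUT&Tag samples for H3K27ac were not analysed here. No stage or tissue had a second RNA library, so the scatter of single libraries around a smooth curve stood in for replicate error. Intervals given for counts and shares cover counting error only. The sources used here do not settle whether the counted strand is that of the transcript, so levels are those of reads assigned to a gene model. The files do not pair the gene identifiers with names.

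The first comparison asked which genes change over normal development. Counts assigned to 8364 genes rose and those to 4496 genes fell by at least 1 log2 unit between the first 4 libraries (egg, 2-, 4- and 8-cell) and the last 4 (early gastrula, late gastrula, prism and pluteus). The median level of the rising genes went from 0.154 CPM (counts scaled by library size and TMM factor) in the egg to 1.04 in early blastula, 3.5 in early mesenchyme blastula and 7.52 in pluteus, and 1841 of them had 0 counts in each of the first 4 libraries. The median of the falling genes was 22.2 CPM in the egg and between 25.6 and 29.7 CPM from the 2- to the 128-cell stage, then 15.3 in blastula, 6.78 in early mesenchyme blastula and 7.55 in pluteus. In 5132 of the rising genes every one of the last 4 libraries lay above every one of the first 4, and in 3667 of the falling genes every one lay below. Over all 22940 tested genes 23.2% were separated upward and 17.9% downward in this way, where a chance arrangement of 4 against 4 libraries gives 1.43% in each direction. That value takes the libraries as interchangeable. Neighbouring stages are not, so any drift over the libraries, such as culture, could also exceed it.

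In all, 14841 of the 22940 genes tested had a trend at an adjusted p under 0.05 in edgeR's quasi-likelihood test on a spline over stage order. The fitted maximum of 4004 of them was in pluteus, of 1890 in early gastrula and of 1588 in the egg. A test with simulated changes recovered 75 of 100 genes changed 4-fold but 4 of 100 changed 2-fold, so a gene without a call was not shown to be steady. The simulated changes were placed in genes with a mean above 100 counts, so power for genes with fewer counts was not measured. Restricting the test to genes with at least 5 CPM in 3 libraries left 4718 rising genes. The rising share of rising and falling genes was 65.0%, against 54.8% without the egg library (5796 and 4783 genes). It was 51.5% (6090 and 5743 genes) in the 14 libraries with at least 3.12% of their counts on Scaffold_2421. This setting, chosen after seeing the data, leaves out pluteus. The early and late means still covered all stages, so the curve at a left-out egg or pluteus stage was extrapolated. Without the prism library, which stood apart from its neighbours, 7700 genes rose and 5015 fell. The main fit used counts as deposited, which were all even in the developmental libraries. Dividing them by 2, also chosen after seeing the data, left 20219 genes tested. Of these 7118 rose and 5076 fell, a rising share of 58.4%.

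PL32582, on the plus strand of Scaffold_641 from 10821884 to 10827807 in 6 exon records, had 0 counts in each library from egg to 16-cell stage. Scaled by library total, as for all 4 named genes, it reached 1.405 CPM at the 32-cell stage (95% exact Poisson interval 0.748 to 2.4), 74.78 CPM in swimming blastula and 19.61 CPM in pluteus. Its level over the last 4 libraries was at least 154-fold higher than over the first 4, against a floor of 3 halved counts in each library (edgeR adjusted p = 2.05e-08). PL00926, on the minus strand of Scaffold_3425 from 35821543 to 35822927, likewise had 0 counts through the 16-cell stage. It reached 67.45 CPM in early mesenchyme blastula (62.7 to 72.4). After this it was lower again, at 10.41 CPM in early gastrula, 3.917 in late gastrula, 18.01 in prism and 7.346 in pluteus. Its level over the last 4 libraries was at least 33.1-fold higher than over the first 4, against the same floor (edgeR adjusted p = 1.75e-06).

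PL35093, on the plus strand of Scaffold_3430 from 11743892 to 11747987, fell from 1917 CPM in the egg to 254.3 in early blastula, 30.41 in swimming blastula and 1.011 in pluteus (0.566 to 1.67). Its fitted log2 change was -9.58 (SE 0.563, edgeR adjusted p = 6.54e-10), and its pooled level was 806-fold higher in the first 4 than in the last 4 libraries. It stood at 112.9 CPM in adult ovaries, 48.65 in bodywall, 9.111 in gut, 8.439 in lantern and 0.5259 in tubefeet. PL40292, on the plus strand of Scaffold_3435 from 23881235 to 23888047, was higher at the 2-cell stage (143.8 CPM) than in the egg (34.96 CPM), and fell to 0.2022 CPM in pluteus, with a fitted log2 change of -9.12 (SE 0.589, edgeR adjusted p = 1.41e-09). For all 4 genes the 27 other settings and left-out libraries kept the direction and an adjusted p under 0.05.

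**Figure D1:**
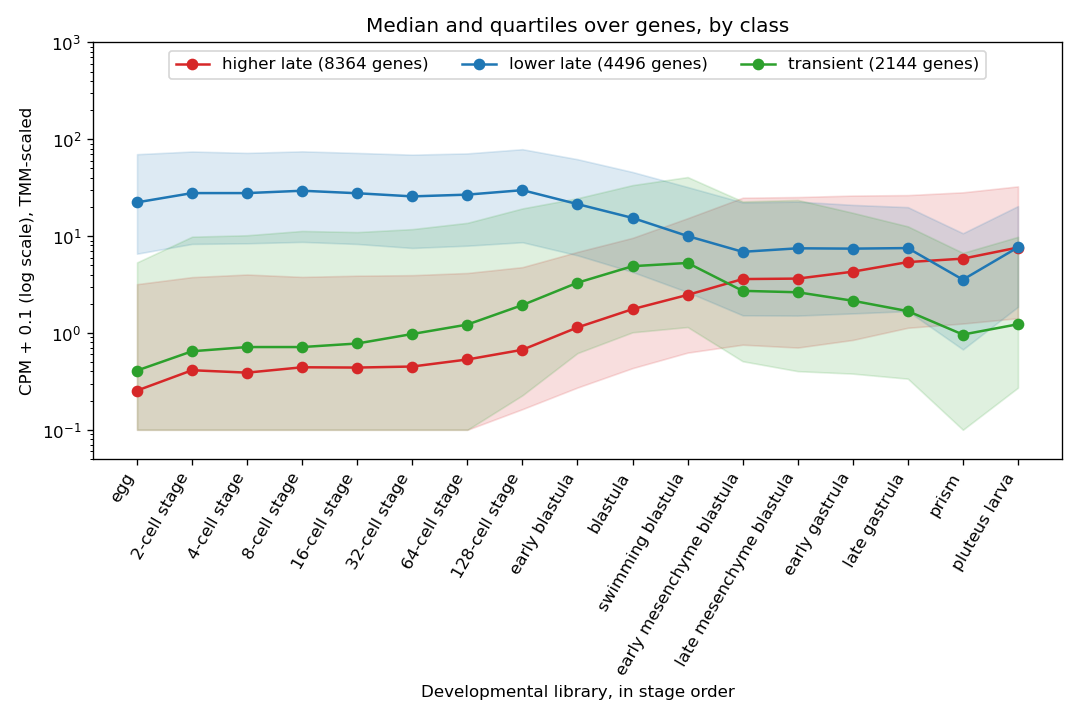
TMM-scaled CPM plus 0.1 on a log axis against the 17 developmental libraries in stage order, as the median (line) and quartiles (band) over the genes of each class. The medians of rising and falling genes are 0.154 and 22.2 CPM in the egg and 7.52 and 7.55 CPM in pluteus.

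A smaller class, called transient here, was raised in mid development. In 2144 genes the highest point of the fitted curve between the 16-cell stage and late mesenchyme blastula lay at least 1 log2 unit above its mean over the first 4 and over the last 4 stages, with a median of 5.18 CPM in swimming blastula against 0.309 in the egg and 1.13 in pluteus. In 1993 of them the whole curve was highest within this window and in 151 outside it, including 23 in the egg and 32 in pluteus. Of the 2144, 944 also rose and 415 also fell between the ends. This count was unsteady: 4134 genes met it without the pluteus library, where the curve at pluteus was extrapolated, and 1058 among genes with at least 5 CPM in 3 libraries. One of 39 random orders of the libraries gave 2639 such genes, more than the real order.

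Between consecutive libraries, few genes moved during cleavage, where the 2- to 32-cell libraries lay between 2 and 5 hours after fertilization. At least 4-fold changes were counted in 1 gene between the 2- and 4-cell stages, in 0 between 4- and 8-cell, in 5 between 8- and 16-cell and in 41 between 16- and 32-cell, of which 40 were higher later. From the 128-cell stage to early blastula 207 genes were higher and 26 lower. The step from swimming to early mesenchyme blastula, 12 to 18 hours, held 1024 higher and 687 lower genes, or 803 and 848 when scaled by library size alone, whereas early and late mesenchyme blastula differed in 11 genes. These 2 mesenchyme blastula libraries had 0.292% and 0.608% of their counts on Scaffold_2421, against 3.67% in swimming blastula and 3.32% in early gastrula, so the step also separates libraries that differ in this share. The step from late mesenchyme blastula to early gastrula, which crosses this difference the other way, held 216 higher and 194 lower genes. From egg to 2-cell stage 326 genes were higher and 74 lower, or 826 and 12 with library-size scaling. With 1 library per stage these counts have no test.

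The steps into and out of prism were the largest, with 3359 and 3632 genes, and they involve a library that stood apart. These steps were also the longest, from 24 to 36 and from 36 to 48 hours, and step counts were not adjusted for time. Prism had 12637 genes at 1 CPM or more against 17014 in late gastrula and 17397 in pluteus, a TMM factor of 0.3667, a residual SD around the curve of 1.459 log2 units against 0.495 to 0.932 in the other libraries, and 49.4% of its counts on its 100 highest genes, against 24.6% to 38.2% in the other developmental libraries. Scaled by library size alone, the step from late gastrula to prism held 304 higher and 6707 lower genes in place of 1317 and 2042, and the step from prism to pluteus 6930 higher and 189 lower in place of 2492 and 1140.

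**Figure D2:**
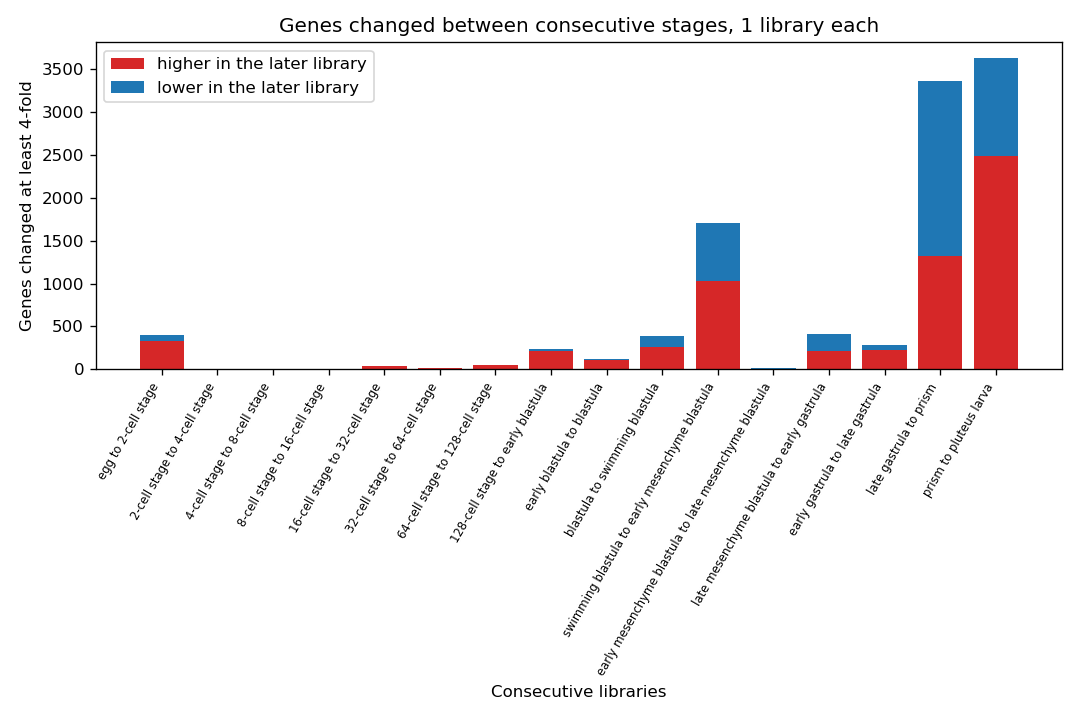
Number of genes with a ratio of at least 4 in TMM-scaled CPM (prior 0.5 CPM, at least 5 CPM in the higher library) for each pair of consecutive libraries, split by direction, 1 library per stage. The bars into and out of prism hold 3359 and 3632 genes and that from swimming to early mesenchyme blastula 1711.

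Among the adult tissues, genes at 5 CPM or more in 1 tissue and at least 8 times the next tissue numbered 407 in tubefeet, 267 in ovaries, 260 in Aristotle's lantern, 95 in gut and 24 in bodywall. The gut and bodywall libraries shared much of their expression, with a Spearman correlation across genes of 0.927, against 0.618 to 0.782 for the other adult pairs. Without the bodywall library 600 genes were restricted to gut and 475 to ovaries, and without the gut library 281 to bodywall. Library-size scaling gave 648 genes in tubefeet, 122 in lantern, 61 in bodywall and 21 in gut, and a prior of 2 CPM gave 220 in tubefeet, 159 in ovaries and 6 in bodywall.

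The egg library was closer to adult ovaries than to any other adult tissue over the 22940 genes of the trend test. Spearman correlations across genes, which are not independent replicates, were 0.742 with ovaries, 0.618 with bodywall, 0.56 with gut, 0.56 with tubefeet and 0.458 with Aristotle's lantern. This order did not hold over the 5859 genes with at least 1 CPM in every library, where the egg correlated at 0.295 with ovaries, 0.319 with bodywall and 0.305 with Aristotle's lantern. Nor was closeness to ovaries particular to the egg over the 22940 genes. Ovaries correlated at 0.768 with the 2-cell stage, 0.769 with the 4-cell stage and 0.763 with early blastula. Pluteus correlated at 0.721 with ovaries, 0.705 with bodywall and 0.671 with gut.

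ATAC-seq asked where chromatin is open at each stage. The lists held 30683 peaks at the 16-cell stage, 142485 in blastula, 154157 in gastrula, 112026 in prism and 44711 in pluteus. The lists labelled early and late blastula were identical, so the 6 lists hold 5 distinct ones and the blastula list cannot be assigned to either stage. Peaks covered 18.5 Mb at the 16-cell stage, 75 Mb in gastrula and 24 Mb in pluteus, with mean widths between 486.5 and 602.4 bp. The labels give 2 samples at the 16-cell stage, 7 in gastrula, 4 in prism and 2 in pluteus, and 6 for early and 7 for late blastula, whose shared list cannot be tied to a number of samples. The effect of sample number on peak counts was not tested, and no replicate error was available.

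Most peaks of a shorter list had a counterpart in its longer neighbour. All but 2 of the 30683 16-cell peaks overlapped a blastula peak by at least 50% of the shorter peak, as did 99.6% of pluteus peaks in the prism list (exact 95% interval 99.5 to 99.6) and 97.8% of prism peaks in the gastrula list. Of the blastula peaks 78.4% (78.1 to 78.6) were found in gastrula, and 29999, or 21.1%, were in no other list. Peaks moved by 10 kb matched at far lower rates, 12.9% for 16-cell peaks in the blastula list and 11.4% for pluteus peaks in the prism list. Taking the 30683 top-scoring peaks of each list, 78.6% of 16-cell peaks had a counterpart in blastula and 83.4% of prism peaks in pluteus, against 36.9% with the full prism list.

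**Figure D3:**
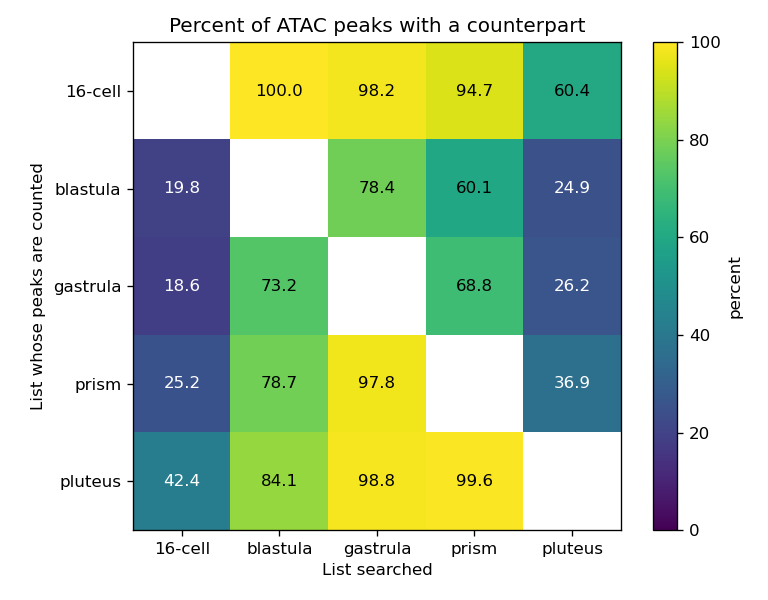
Percent of the peaks of each list (rows) that overlap a peak of another list (columns) by at least 50% of the shorter peak, for the 5 distinct stage lists. Rows of the short 16-cell and pluteus lists reach 98.2% and 98.8% in the gastrula column, while gastrula peaks are found at 18.6% and 26.2% in the 16-cell and pluteus lists.

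Peaks lay near gene starts more often late than early. Summits within 1 kb of an annotated gene start made up 10.1% of 16-cell peaks (9.72 to 10.4), 10.4% in blastula, 10.6% in gastrula, 12.2% in prism and 18.2% in pluteus (17.8 to 18.5). Peaks moved by 10 kb gave 5.64% to 6.25%. With 30683 top-scoring peaks from each list the share was 14.6% in blastula, 18.6% in gastrula and 20.1% in pluteus, so the difference between gastrula and pluteus in the full lists depends on list length. Introns held 31.6% of 16-cell and 33% of gastrula peaks, and exons away from gene starts 3% and 3.72%. PL32582 had a peak at its start in all 5 lists, with a summit at 10821748 in blastula, 136 bp from the start. PL00926 had one in 4 lists, all but pluteus, and neither falling gene had one in any list.

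Genes with a peak at their start had higher levels of assigned reads at every stage compared except the 16-cell stage. In gastrula the median was 3.22 on the log2(CPM + 0.5) scale for 11180 genes with a peak and 1.41 for 11760 genes without. The medians were 3.94 and 1.89 in pluteus, 2.65 and 1.28 in prism, and 2.91 and 1.29 for the blastula list with early blastula RNA. At the 16-cell stage the order was the opposite, 0.88 for 2400 genes with a peak and 1.99 for 20540 without, but with no low-count filter the difference there was 0.13 the other way. Genes are not independent replicates and no test was made.

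**Figure D4:**
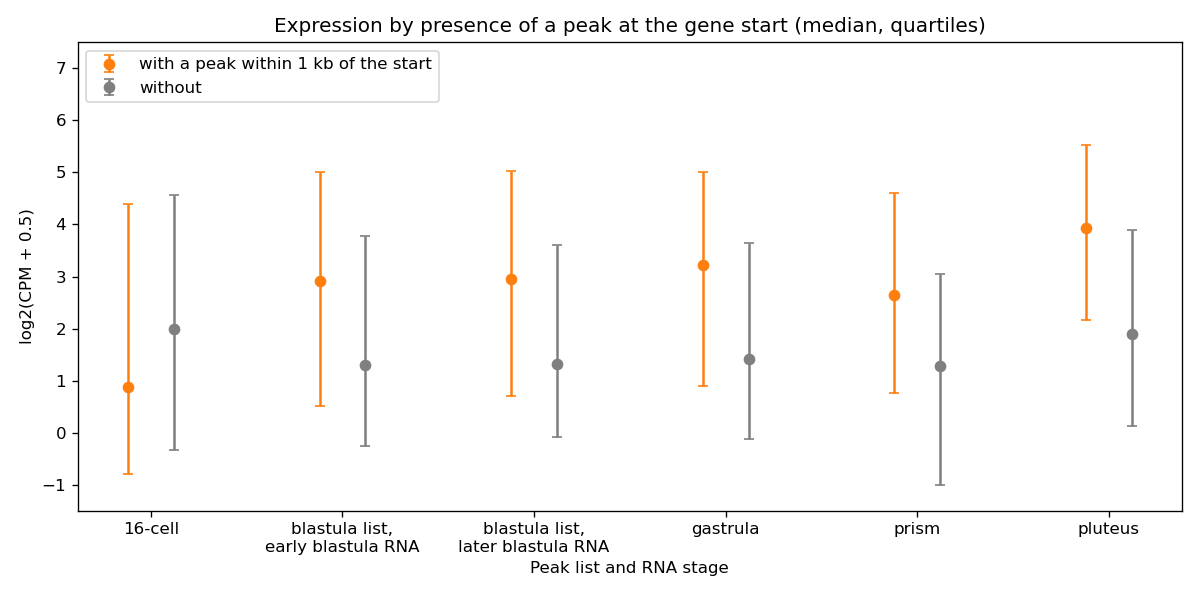
Median (point) and quartiles (bar) of log2(CPM + 0.5) over tested genes with and without an ATAC peak within 1 kb of their start, by peak list and RNA stage. Genes with a peak lie 1.37 to 2.05 log2 units higher at each stage but the 16-cell stage, where they lie at 0.88 against 1.99.

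Gain and loss of a start peak were judged by whether a summit lay within 1 kb of the start. Genes that gained one between the blastula and gastrula lists had a median log2 ratio of 0.31 from early blastula to gastrula RNA, at percentile 100 among 10000 random lists matched on mean expression, whose central 95% ran from 0.02 to 0.17. The 894 genes that lost one had a median of -0.01, at percentile 0.01 of their random lists. Without a low-count filter 1352 genes lost one, at percentile 49.67. Their median and the central 95% of their random lists were then all 0, so equal values put the percentile near 50 and it cannot decide. The 7926 genes that gained one between 16-cell and blastula moved by a median of 0.04, above the random range of 0 to 0.02. Without a low-count filter 9718 genes gained one, at percentile 50, again with the median and the random range all at 0. These gains set 30683 against 142485 peaks, and with equal numbers of top-scoring peaks 2242 genes gained one, with a median of 0.08 at percentile 100. The 100 genes that lost one there had a median of 0.26, at percentile 99.48, but lay at 81.8 among genes with a peak in the 16-cell list, a background chosen after seeing the data. A 16-cell start peak of each of these 100 genes overlapped a blastula peak, whose summit then lay outside the 1 kb window. From gastrula to prism the 233 genes that gained a peak had a median of -0.16 against -0.57 in the random lists, at percentile 99.95, and a prism start peak of 48.1% of them overlapped a gastrula peak. The 1438 that lost one lay at percentile 90.44, but at 0.5 with equal numbers of top-scoring peaks and at 99.96 among genes with a peak in the gastrula list, so they have no settled direction. From prism to pluteus those that gained one lay at percentile 76.19, and 95% of them had a pluteus start peak that overlapped a prism peak, and the 3154 that lost one lay at percentile 0, with a median of 0.54 against 0.67. These losses set 112026 against 44711 peaks, and with equal numbers of top-scoring peaks 445 genes lost one, at percentile 0.31. The comparisons from gastrula to prism and from prism to pluteus use the prism library.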

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

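Settings on halved counts, on Scaffold_2421, on the bodywall or gut library, on the 22-library and all-gene sets and on random lists from genes of the same earlier state were chosen after seeing the data. Counts of genes with a trend (10597 to 16180) and of falling genes (3377 to 5252) stayed within 1.5 times the reported ones under all planned settings other than left-out libraries, and with each library left out (13853 to 16104 and 4155 to 5146). With at least 5 CPM in 3 libraries, which tests 13386 genes, 4718 genes rose and 1058 were transient. Transient genes numbered 3998 in the 14 libraries with a high Scaffold_2421 share, which lack pluteus. With a library left out they numbered 1637 (without egg) to 4134 (without pluteus). In these settings the curve at the missing egg or pluteus stage was extrapolated. How far this accounts for the differences was not tested.

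Step changes summed to 18254 with library-size scaling and 6559 with a prior of 2 CPM, against 10661. Library-size scaling gave 21 gut, 61 bodywall, 648 tubefeet and 122 lantern genes, and a prior of 2 CPM gave 159 ovary, 6 bodywall and 220 tubefeet genes. Leaving out bodywall gave 475 ovary and 600 gut genes, and leaving out gut 281 bodywall genes. The correlation of egg with ovaries was 0.295, no longer the highest, over genes at 1 CPM everywhere, 0.487 over genes passing a 22-library filter and 0.783 over all genes with a count.

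Peaks above the median score numbered 11293, 70934, 82200, 56930 and 20674 in stage order. With 50% reciprocal overlap the shares were 70% of 16-cell in blastula, 15.1% in reverse, 66.4% of blastula in gastrula, 61.4% in reverse, 63.7% of gastrula in prism, 87.7% in reverse, 30.9% of prism in pluteus and 77.3% in reverse. With equal numbers of top peaks they were, in that order, 78.6%, 70.6%, 67.1%, 67.2%, 90.2%, 91.4%, 83.4% and 88.8%. Shares near starts within 0.5 kb were 6.33%, 6.86%, 7.08%, 8.54% and 14.1% in stage order, within 2 kb 15.9%, 16.5%, 16.5%, 18.2% and 24.2%, and with equal numbers 14.6%, 18.6%, 18.8% and 20.1% from blastula on.

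The difference in median log2 level by start peak reversed at the 16-cell stage without a filter, to 0.13. Elsewhere it stayed positive. For the blastula list with early blastula RNA it was 1.92 within 0.5 kb, 1.27 within 2 kb, 1.83 with equal numbers and 2.3 without a filter, with later blastula RNA 1.9, 1.3, 1.87 and 2.17, and in gastrula 2.06, 1.48, 2.28 and 2.72. In prism it was 1.28 within 2 kb, 1.74 with equal numbers and 3.04 without a filter, and in pluteus 1.93 within 2 kb and 3.81 without a filter.

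Percentiles of genes losing a peak, judged by summit position, were unsteady. From 16-cell to blastula with early RNA they were 96.21 within 2 kb, 79.84 with equal numbers, 49.64 without a filter and 81.8 against genes of the same earlier state, and with later RNA 66.48, 93.37 and 66.22 for 2 kb, equal numbers and same state. From blastula to gastrula they were 49.67 without a filter with early RNA, and 16.78 within 2 kb and 50 without a filter with later RNA. From gastrula to prism they were 0.5 with equal numbers and 99.96 against the same earlier state, which lie on opposite sides. Genes gaining a peak lay at 50 from 16-cell to early blastula without a filter and at 99.62 from prism to pluteus within 2 kb. For the values of 49.64, 49.67 and 50 without a filter, the observed median and the random range were all 0 after rounding. Equal values put these percentiles near 50, so they cannot decide. The causes of the other differences were not tested. The set tests planned for the fixed gene lists were not run.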

Other observations

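The tests of tissue-restricted sets, of library order, of prism depth (in place of a planned one on genes at 1 CPM that hardly responds to depth), of gut RNA in bodywall and of a longer peak list were chosen after the results were seen. Adult tissue-restricted genes were followed over development, with no test of one set against another. Of 265 tested ovary-restricted genes 120 fell and 64 rose, and 39 of 65 gut genes and 109 of 175 lantern genes rose, against 36.5% rising and 19.6% falling among all tested genes. The low-count filter had kept 265 of 267 ovary, 65 of 95 gut and 175 of 260 lantern genes. A gene near 0 counts early could pass it only through later libraries, which favours a rise among the genes tested. Tested as sets, ovary genes moved down (camera adjusted p = 2.91e-06 with a preset correlation, adjusted p = 0.0437 with an estimated correlation), but with an estimated correlation their adjusted p was 0.0634 under RLE scaling and 0.102 without the prism library, both by camera. Lantern and gut genes moved up with the preset correlation (camera adjusted p = 1.91e-05 and 0.00105) but not with an estimated one (adjusted p = 0.16 and 0.0814). Without the prism library 89 of 169 lantern and 33 of 62 gut genes rose (camera adjusted p = 0.000877 and 0.00477 with the preset correlation, adjusted p = 0.164 and 0.138 with an estimated one). The lantern median was 3.86 CPM in prism against 1.07 in late gastrula and 1.18 in pluteus after TMM scaling, and 1.69, 1.28 and 1.35 CPM of the library total. The gut median was 2.9, 0.916 and 2.07 in the same stages after TMM scaling, and 1.26, 1.09 and 2.36 CPM of the library total. Of 295 tubefeet genes 115 rose and 37 fell, and of 8 bodywall genes 5 rose (camera adjusted p = 0.179 and 0.12 with the preset correlation).

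Counts on Scaffold_2421, which has 9 gene models, differed between libraries. It took 3.12% to 7.56% of counts in 14 developmental libraries, but 0.292% in early mesenchyme blastula, 0.608% in late mesenchyme blastula, 0.209% in pluteus and 0.0838% to 0.399% in the 5 adult libraries. The 4 highest gene models on it held at least 99.7% of its counts in each library.

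In 40 orders of the 17 libraries, the real one included, only 1, the real one, reached 14841 genes with a trend (highest other 2898). Only 1 reached 8364 rising genes (highest other 1094) and only 1 reached 4496 falling genes (highest other 2063). None of the 39 random orders thus reached the real counts for these. The orders cannot tell a change with stage from any other smooth drift over the libraries, such as culture. For transient genes 2 of 40 orders reached 2144 (highest other 2639), so chance order cannot be excluded.

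The prism library stood apart from late gastrula and pluteus. The number of counts does not account for this, since the neighbours would have to be thinned to 12.7% of the prism total or less to have as few as 19105 genes with a count, and gene length does not either, since the Spearman correlation with the mean of the neighbours was 0.837 before and 0.827 after removing the length trend. Lantern RNA at the median share of 1.25% is argued against by 25.5% of 106 lantern-restricted genes lying more than 10-fold below it, but over the 5859 genes at 1 CPM in every library prism correlated across genes at 0.765 with lantern, 0.742 with late gastrula and 0.734 with pluteus (0.615, 0.82 and 0.817 over the 22940 genes of the trend test). The 260 lantern-restricted genes took 1.34% of prism, 0.759% of late gastrula and 1.19% of pluteus counts. A smaller share of lantern RNA, RNA quality, library preparation with few distinct molecules behind the counts and a real change of stage stay open, untested.

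The bodywall library may hold gut RNA. Of 295 genes restricted to gut among the other 4 adult libraries, 89.2% lay within 4-fold of their median share in bodywall, 63.1% of the gut level, where the median share was 12.4% for ovary genes, 0.893% for tubefeet genes and 1.56% for lantern genes. Ovary genes lay even closer to one share, with 96.4% within 4-fold. The 89.2% lies between the bounds set for and against a mixture, and the 96.4% of ovary genes would meet the bound for a mixture. The measure thus does not single out gut RNA, and a mixture and cell types common to both tissues cannot be told apart.

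Nearly every 16-cell peak was in the blastula list. The still longer gastrula list lacked 548 of the 16-cell peaks and the blastula list 2. Gastrula is also a later stage, so this comparison cannot isolate list length. A candidate explanation is that 16-cell libraries were among those called for the blastula list. Of the 16-cell peaks, 100% after rounding had a blastula peak of at least the same score, against 96.3% in gastrula, 88.4% in prism and 24.3% in pluteus. The lists also differ in number of samples, whose effect on scores was not tested. Chromatin that opens by the 16-cell stage and stays open through blastula could also place a blastula peak at nearly every 16-cell peak. Whether it would give scores at least as high was not tested, so this explanation is not excluded.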
